A study of Mus musculus with 7 samples.

How the data were processed

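The series holds 7 single-cell libraries of C57BL/6 mouse cells, 1 per population, made from cells dissociated with trypsin-EDTA on the ddSEQ droplet system with a 3′ whole-transcriptome kit and UMIs. The populations were primary oligodendrocyte progenitors (pOPC), embryonic fibroblasts (MEF), cerebral pericytes (PC), and MEF or PC transduced with Olig2 and Sox10 (MEF-2F, PC-2F) or with Olig2, Sox10 and Nkx6-2 (MEF-3F, PC-3F). The submitters' processing notes name bcl2fastq 2.19.1.403, UMI-tools 0.5.3, STAR 2.5.3a, featureCounts 1.6.1 of the Subread package and the mm10 genome, without their order. Gene coordinates were taken from the GENCODE annotation of GRCm38, which is the same assembly as mm10.

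The deposited values are of an unnamed kind (unit: other), not UMI counts as they stand, and how they arose is not stated. Each deposited value was read as the place, counted from 0, of a UMI count in the list of all counts that occur, sorted as text (0, 1, 10, 100, 11 and so on), so that a gene with 2 UMIs can carry a large code. In all libraries the codes run from 0 to their maximum without gaps, and in every barcode the most frequent code above 1 was the one read as 2 UMIs. Over the 19 lowest counts 0 to 2 of 18 steps in frequency went up, depending on the block, against 3 to 8 of 18 over the 19 lowest codes, but the decoding favours smooth frequencies, so this supports the reading only in part. This reading is an inference from the values that no label states, every level given here depends on it, and the simulations below assume it and do not check it. The matrices of PC, MEF-2F and MEF-3F join 2 blocks of barcodes, seen where the alphabetical order starts again, and each block has its own code list. The labels do not explain the blocks, and they were not counted as replicates; values within blocks are given where they matter. Counts were recovered by aligning, for each block, the observed codes to the text-sorted whole numbers, with a smooth model of how frequent each count is, and each code was given its most probable count where that had a probability over 0.5 and the rounded expected count otherwise. Codes whose count had a probability above 0.99 held from 92% (second block of MEF-2F) to 98.2% (second block of MEF-3F) of UMIs. Codes simulated from known counts were decoded to the exact count in 99.9% to 100.0% of non-zero entries, depending on the block. Large counts are the uncertain part, and the largest error of a gene's summed count was 15.3% in the first block of PC and 14.8% in the second block of MEF-2F.

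The plan written before the data were examined fixed the comparisons, the gene lists, the rule for named genes and the alternatives, and it took the values for UMI counts, which they were not. Barcodes with at least 500 UMIs and under 20% mitochondrial UMIs were kept, 1124 of 1140 over 17784 genes. The other barcodes were left out for low counts, and mitochondrial shares per library ran from 0.140% in PC to 1.62% in PC-2F. UMIs were summed over the kept cells of each library and divided by the library total to give CPM. With 1 library per population no test between populations exists, so no p-value is given. Levels carry exact Poisson intervals, ratios of levels carry exact intervals from the binomial distribution conditional on both counts, and shares carry exact (Clopper-Pearson) binomial intervals, all at 95%. These cover counting error only, not the spread between cultures, and UMI counts of 1 cell are not independent of its state. A log2 ratio uses 0.5 UMIs added per library, a printed fold is the plain ratio of levels, and a gene with 0 UMIs in 1 library is given as a lower bound with that library set at 3 UMIs. A list member was measured at 10 UMIs and 20 CPM or more in 1 of the 2 libraries, and called higher or lower at 2-fold or more with an interval that excludes 1. A list's median was set against 10000 random lists drawn from 20 expression bins, as a percentile, and lists with fewer than 3 measured members got no median. Counts of genes by size took those at least 4-fold apart whose interval lay wholly beyond 2-fold.

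For each comparison the genes named were the 12 highest and 12 lowest ratios at 100 CPM and 30 UMIs or more with an interval wholly beyond 2-fold, the 4 measured members of each list with the largest ratios, and always Olig2, Sox10, Nkx6-2, Olig1, Pdgfra, Cspg4, Mbp, Col1a1, Col1a2, Thy1, Acta2, Rgs5 and Pdgfrb. Mitochondrial, ribosomal protein and unnamed (Gm, Rik) genes were left out of this rule, and some genes that it names are not shown. Levels of Sparc, Fabp7, Trf, Apod, Igf2, Elavl4, Dcx and Gap43 in libraries outside the comparison that named them, and the genes given per cluster, are shown for context. The 24 fixed lists covered OPC, oligodendrocyte differentiation, fibroblast, pericyte, contractile, TGF-beta and YAP target, cell cycle, cholesterol synthesis, interferon response, p53 and senescence, immediate early and heat shock, glycolysis and hypoxia, imprinted growth, neuron, astrocyte, microglia and macrophage, endothelial, Schwann and neural crest, myogenic, chondrogenic and osteogenic, epithelial, Hox, sex-linked and transduced factor genes.

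For retained and acquired shares, donor and pOPC cells were split at random into 2 parts. Genes at least 4-fold apart between donor and pOPC at 50 CPM or more were chosen in the first part and measured in the second, and the median log2 ratio of the converted library was divided by that of the second part. For the weight per cell, each cell with at least 1000 UMIs was thinned to 1000 UMIs and fitted as a multinomial mixture of the pOPC, MEF and PC profiles by expectation maximisation. Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 at resolution 0.5 on 30 principal components of log-normalised counts over 2000 variable genes, with 15 neighbours per cell, without batch correction. Cell types were named only from marker lists fixed in the plan, which set no number of markers; a name was given, after the values were seen, where 3 or more markers were among a cluster's top 10 genes by fold. Other computing used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.

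The procedure was tested on simulated data. Of 200 genes simulated 4-fold apart 42.5% to 52% were found, so genes near the threshold are missed about as often as found. Of those simulated 8-fold apart 98% or more were found, with at most 1 false call. The simulated counts held counting error only, so false calls from spread between cells, blocks or cultures are not covered. Between the 2 blocks of a library, the genes counted higher and lower in the first block were 31 and 5 (PC), 6 and 23 (MEF-2F) and 50 and 24 (MEF-3F). Mixtures of 25, 50 and 75% pOPC came back as 24.4, 50.2 and 74.6%. A library simulated at 50% of the log2 distance came back at 50.5% (MEF) and 51.3% (PC) for retained genes, but at 60.1% (MEF) and 53.3% (PC) for acquired genes.

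Alternatives fixed in the plan changed 1 choice at a time: cells (1000 UMIs or more, all barcodes, without barcodes called doublets by Scrublet), scaling (trimmed-mean factors, CPM without the 20 most abundant genes and mitochondrial and ribosomal protein genes, libraries thinned to the smallest total), 5 CPM added to a ratio, minimum level (none, or 100 CPM), mean of per-cell CPM, an 8-fold choice of genes, another random split, 500 UMIs per cell, least squares for the mixture, resolution 1.0 and no cell cycle genes. The trimmed-mean factors were computed directly in Python from their published definition, since the deposited values are codes. Added after the data had been seen were each block alone and the single most probable count of each code.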

Results

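Single-cell transcriptomes were collected from 7 mouse cell populations to ask how far 2 kinds of donor cell take on the expression profile of oligodendrocyte progenitor cells after forced expression of transcription factors, and what they keep of the donor. The cells came from C57BL/6 mice, and barcoded 3′ ends of transcripts were counted by unique molecular identifiers (UMIs) after droplet capture on the ddSEQ system. One library held primary oligodendrocyte progenitor cells from brain (pOPC), the dividing glial precursors that give rise to myelinating oligodendrocytes. The donors were embryonic fibroblasts (MEF) and cultured cerebral pericytes (PC), the mural cells of brain capillaries, each sequenced without transduction. The converted populations had received 2 factors (Olig2 and Sox10; MEF-2F and PC-2F) or 3 factors (Olig2, Sox10 and Nkx6-2; MEF-3F and PC-3F). Each population was 1 library, so no comparison below has a replicate check and none was tested; each sets 2 libraries side by side, not the conditions. Levels (CPM) are a gene's UMIs summed over cells and scaled to the library total. Ranges beside a level or a fold are exact 95% intervals that cover counting error only, and ranges beside a list's median are intervals of that median over the list's genes, which are not independent replicates. After barcodes with fewer than 500 UMIs were left out, the libraries held 134 (pOPC), 131 (MEF), 290 (PC), 82 (MEF-2F), 161 (MEF-3F), 179 (PC-2F) and 147 (PC-3F) cells. Total UMIs ranged from 230471 in MEF-2F to 1292653 in PC, and the median per cell from 1866 in MEF-3F to 6259 in PC-2F. At these totals 3 UMIs, the limit that a count of 0 allows, correspond to 2.32 CPM in PC and 13 CPM in MEF-2F, so low genes are resolved least well in MEF-2F.

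The transduced genes came first, as a check of the labels. Olig2, a basic helix-loop-helix factor of the oligodendrocyte lineage, had no UMI in MEF or PC, against 1656 CPM (1558 to 1759.7) in pOPC. It stood at 65.1 CPM (36.4 to 107) in MEF-2F, 329 CPM (279 to 386) in MEF-3F, 191 CPM (167 to 217) in PC-2F and 88.2 CPM (66.6 to 115) in PC-3F. Sox10, the glial and neural crest HMG-box factor, was at 12.7 CPM in MEF and 0 in PC, and at 130.2 CPM (87.8 to 186), 244 CPM (201 to 294), 251 CPM (223 to 281) and 216 CPM (181 to 255) in MEF-2F, MEF-3F, PC-2F and PC-3F, against 591 CPM in pOPC. Nkx6-2 gave at most 2 UMIs in any library, PC-3F and MEF-3F included. A 3′ tag need not fall on a virally delivered coding sequence, so these counts cannot tell vector from endogenous transcript, and the Nkx6-2 counts check nothing. With each cell thinned to 1000 UMIs, Olig2 was seen in 76.7% of pOPC cells, 9.33% of MEF-2F, 22.9% of MEF-3F, 16.9% of PC-2F and 8.22% of PC-3F cells. The median depth before thinning was 3958 UMIs in pOPC, 4648 in MEF, 3775 in PC, 2411 in MEF-2F and 4124 in PC-3F. None of the 129 MEF cells and 267 PC cells thinned to 1000 UMIs held an Olig2 UMI, with upper exact binomial bounds of 2.82% and 1.37%. Without thinning the shares were 93.3% in pOPC, 15.9% in MEF-2F, 38.5% in MEF-3F, 45.8% in PC-2F and 25.2% in PC-3F. In the GRCm38 mouse assembly Olig2 lies on chromosome 16 from 91225457 to 91228677, close to Olig1 (91269772 to 91271933 on the same chromosome), Sox10 on chromosome 15 from 79154908 to 79165240 and Nkx6-2 on chromosome 7 from 139579376 to 139582797.

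**Figure D1:**
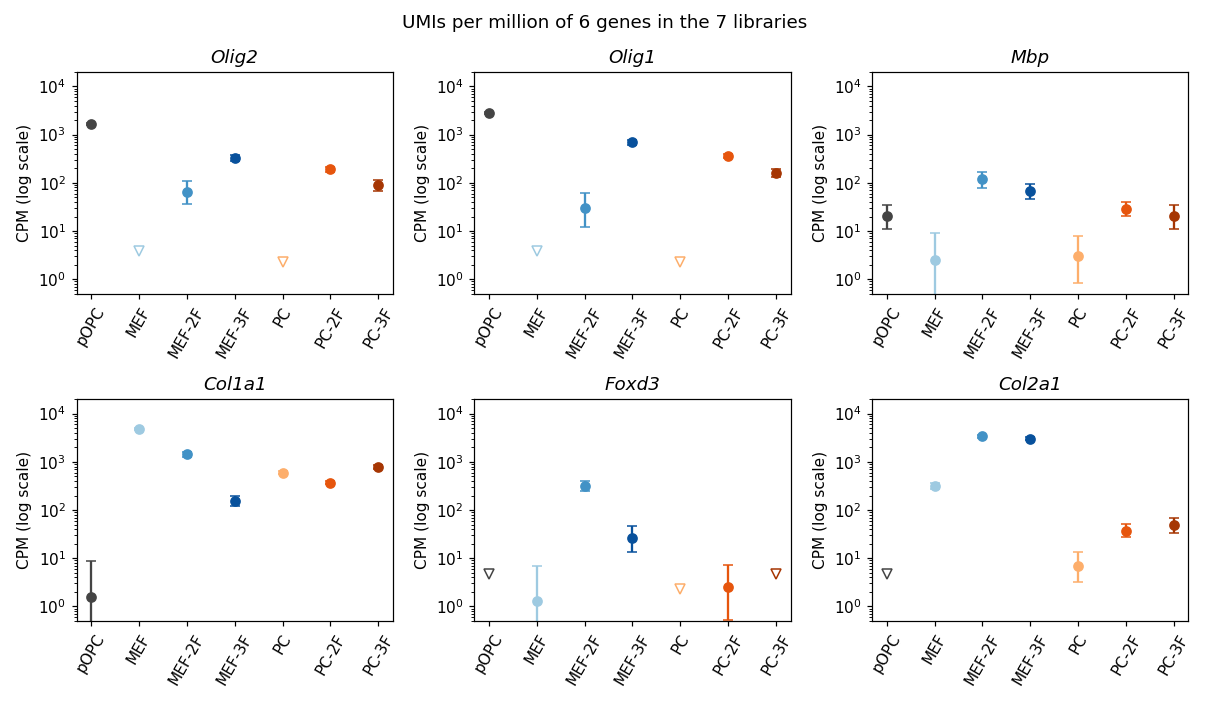
Level in CPM (log axis) of 6 genes in each of the 7 libraries; circles are values, bars are exact 95% Poisson intervals (counting error only), and open triangles mark the limit of 3 UMIs where the count was 0. Olig2 and Olig1 were at 0 in both donors and present in every converted library, while Foxd3 and Col2a1 were highest in MEF-2F.

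Measured genes of the OPC programme were mostly higher in each converted library than in the library of its donor cell type, the comparison that asks whether conversion brings this programme. In MEF-2F all 11 measured members of the OPC list were higher than in MEF, with a median log2 ratio of 6.30 (2.02 to 9.34). In MEF-3F all 17 were higher, with a median of 7.19 (5.31 to 8.75). PC-2F had 16 of 17 members higher and 1 lower than PC, median 7.90 (5.99 to 8.44), and PC-3F had 14 of 15 higher and 1 lower, median 8.32 (6.86 to 8.85). All 4 medians stood at percentile 100 among 10000 random lists matched on expression. A member low in both libraries was not measured, and one nearly absent from the donor was measured only where the converted library was high. These counts thus lean towards higher members and do not show the whole list raised. More members of the list were measured against pOPC, in each converted library, as given below. Ednrb, an endothelin receptor gene of glial and neural crest progenitors, was at 2083 CPM (1901 to 2278) in MEF-2F against 1.27 CPM in MEF, and within MEF-2F at 3855 CPM in the Schwann-like cluster 9 of the joint clustering and 231 CPM in cluster 1. The Schwann and neural crest list was above the donor as well, with medians of 4.91 (MEF-2F), 2.81 (MEF-3F), 7.28 (PC-2F) and 7.75 (PC-3F). The brain proteoglycan gene Bcan was at least 107-fold higher in MEF-2F, at least 190.4-fold higher in MEF-3F, at least 123-fold higher in PC-2F and at least 82.8-fold higher in PC-3F. Olig1, the paralog of Olig2, was at least 181-fold higher in MEF-3F, at least 156-fold higher in PC-2F and at least 68.6-fold higher in PC-3F than in the donor. The progenitor factor gene Sox2 was at least 50.3-fold higher in MEF-2F and at least 87.2-fold higher in MEF-3F, and Fabp7, which encodes a fatty acid binding protein of radial glia and OPCs, was at 887 CPM (803 to 977) in MEF-3F against 1.27 CPM in MEF. Pdgfra, the growth-factor receptor gene that marks OPCs, was at 371 CPM (337 to 407) in PC-2F and 537 CPM (482 to 597) in PC-3F against 88.2 CPM in PC. In the MEF-derived libraries it was at 17.4 CPM in MEF-2F and 107 CPM in MEF-3F, below the PC-derived libraries, against 8.86 CPM in MEF. Many of these genes had no UMI in the donor, and with such genes set at the limit of 3 UMIs the 4 medians were 5.24, 5.81, 5.30 and 5.73, in the same order. With 5 CPM added to every level the PC-2F and PC-3F medians were 4.27 and 4.68.

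Set against pOPC, the distance left to the primary level, the median of the same list was below 0 in each converted library. The median log2 ratio was -2.90 in MEF-2F (19 of 23 members lower, 2 higher), -1.37 in MEF-3F (14 of 24 lower, 4 higher), -2.62 in PC-2F (17 of 24 lower, 1 higher) and -2.96 in PC-3F (17 of 23 lower, 2 higher). Olig1 was 91.1-fold lower (44.1 to 227) in MEF-2F but 4.03-fold lower (3.57 to 4.56) in MEF-3F. Pdgfra was 2.56-fold lower (2.25 to 2.91) in PC-3F and 79.1-fold lower (30.8 to 291) in MEF-2F, whereas the NG2 proteoglycan gene Cspg4, which pericytes also express, was 2.69-fold higher (2.31 to 3.14) in PC-3F. The PC library itself had Cspg4 at 55.7 CPM, below the 360 CPM of pOPC. The cell cycle list was lower than in pOPC in all 4 converted libraries, with 26 of 26 members lower in MEF-2F (median -3.12), 25 of 26 in MEF-3F (-3.09), 18 of 26 in PC-2F (-1.30) and 19 of 26 in PC-3F (-1.37). Nsg2, which encodes an endosomal protein of neurons, was among the 12 genes furthest below pOPC in all 4 converted libraries (at least 111-fold lower in PC-2F), and the membrane glycoprotein gene Gpm6a in MEF-2F, PC-2F and PC-3F (at least 447-fold lower in PC-2F). The neuronal genes Elavl4, Dcx and Gap43 were at 106, 90.1 and 390.4 CPM in the pOPC library itself.

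Oligodendrocyte differentiation genes were also higher in the converted libraries than in the donors. Against the donor, 10 of 14 measured members were higher in MEF-2F, 15 of 18 in MEF-3F, 17 of 18 in PC-2F and 17 of 18 in PC-3F, with median log2 ratios of 5.27, 4.42, 6.37 and 6.20 (4.61, 3.33, 4.40 and 4.24 with absent genes at their limit). Mbp, a major myelin protein gene, reached 117 CPM (77.2 to 170.4) in MEF-2F and 20.5 CPM (10.9 to 35) in PC-3F, against 20.6 CPM in pOPC. The iron-transport gene Trf, abundant in oligodendrocytes, stood at 5872 CPM (5736 to 6011) in PC-2F and 6181 CPM (5989 to 6377) in PC-3F, where it was 186-fold higher (138 to 257) than in PC, against 213 CPM in MEF-2F, 54.5 CPM in MEF-3F and 0 in pOPC. The lipocalin gene Apod followed the same split, at 1293 CPM in PC-2F and 2085 in PC-3F against 30.4 in MEF-2F and 17.4 in MEF-3F. Within PC-3F it was at 5495 CPM in the 27 cells of cluster 8, where Sox10 was at 13.8 CPM, and at 853 CPM in the main cluster 7. Against pOPC, 9 of 14 members were higher in MEF-2F (median 1.86), 11 of 17 in MEF-3F (1.69), 13 of 18 in PC-2F (2.39) and 13 of 18 in PC-3F (1.65).

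The next comparison asked how much of the donor programme was lost. The MEF library had 1 Xist UMI, while Xist stood at 56.4 CPM in MEF-2F and 61 CPM in MEF-3F. The cultures may thus differ in more than transduction, so no difference from MEF can be given to conversion alone. In MEF-derived cells the contractile list was far below MEF, with 10 of 12 members lower in MEF-2F (median -5.74) and 12 of 12 in MEF-3F (median -4.59). With absent genes at their limit these medians were -3.66 and -4.36. Acta2, the smooth-muscle actin of cultured fibroblasts, was 699.8-fold lower (239 to 3394) in MEF-2F and 32.2-fold lower (27 to 38.6) in MEF-3F. Of the fibroblast list, 13 of 27 members were lower and 5 higher in MEF-2F (median -0.89), and 17 of 26 lower and 2 higher in MEF-3F (median -2.34), both at percentile 0. Thy1 was at least 63.2-fold lower in MEF-3F, the collagen crosslinking enzyme gene Lox at least 190.1-fold lower in MEF-2F, and the collagen I gene Col1a1 3.38-fold lower (3.02 to 3.80) in MEF-2F and 31.1-fold lower (24.6 to 40) in MEF-3F. Targets of TGF-beta and YAP signalling were lower too (8 of 10 in MEF-2F and 7 of 10 in MEF-3F), as were imprinted growth genes (7 of 10 and 7 of 10), with the fetal growth factor gene Igf2 at 6091 CPM in MEF, 0 in MEF-2F and 2.18 in MEF-3F. Of the immediate early and heat shock genes, 8 of 13 were higher and none lower in MEF-2F (median 1.30) and 5 of 14 higher and 1 lower in MEF-3F (median 0.84), with Fos 5.39-fold higher (4.82 to 6.02) and 5.31-fold higher (4.81 to 5.87).

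In PC-derived cells the members of the pericyte list went both ways. Of this list, 3 of 10 members were higher and 3 lower in PC-2F (median -0.03, percentile 42.3), and 2 of 8 higher and 3 lower in PC-3F (median -0.05). Over 13 alternative settings the median of the list ran from -0.98 to 1.25 in PC-2F and from -1.03 to 0.73 in PC-3F, so its sign is not settled. The receptor gene Pdgfrb was 4.12-fold lower (3.31 to 5.17) in PC-2F and 2.66-fold lower (2.10 to 3.41) in PC-3F, while Mcam was 66.8-fold higher (36.1 to 140.1) and 48.7-fold higher (26 to 103). These pooled folds join unlike cells: Pdgfrb was at 2.04 CPM in the main cluster of PC-2F and 6.46 CPM in that of PC-3F, but at 448 and 545 CPM in their cells of cluster 8, against 343 CPM in PC. Rgs5, a marker of pericytes in tissue, had no UMI in the PC library itself and stood at 46.7 CPM in PC-2F and 1.58 CPM (1 UMI) in PC-3F. The fibroblast list went both ways, with 8 members higher and 6 lower of 22 in PC-2F and 8 higher and 6 lower of 23 in PC-3F: Dcn was at least 205-fold higher and Postn 158-fold higher (91.7 to 297) in PC-3F, but Fbln2 was 21.2-fold lower (15 to 31.2). Dcn in PC-3F came almost wholly from cluster 8, at 2036 CPM against 12.9 CPM in the main cluster. The pericyte list in MEF-derived cells had medians of -0.22 (MEF-2F) and -1.05 (MEF-3F). Among genes far below PC were the keratin genes Krt19 (at least 127-fold lower in PC-2F) and Krt20 (at least 31.6-fold lower in PC-3F) and the mesothelial marker gene Msln (at least 53.8-fold lower in PC-2F). Among the highest were Lcn2 (at least 1436-fold higher in PC-2F), the collagen IX gene Col9a1 (at least 777-fold higher in PC-2F and at least 1584-fold higher in PC-3F) and the neuregulin receptor gene Erbb3 (at least 322-fold higher in PC-3F). Counted by size alone, genes at least 4-fold above the donor numbered 519 (MEF-2F), 663 (MEF-3F), 671 (PC-2F) and 708 (PC-3F), and those at least 4-fold below 297, 438, 348 and 396, of 7542 to 8546 measured genes. With a minimum of 100 CPM in place of 20 CPM, the numbers above the donor were 284, 221, 245 and 260 and those below 187, 216, 134 and 166, so the counts describe pairs of libraries and do not rank them. Scaled by a trimmed mean of log ratios, all ratios to the donor shift by a further -0.28 (MEF-2F), -0.29 (MEF-3F), -0.11 (PC-2F) and -0.14 (PC-3F) on the log2 scale, and those of MEF and PC to pOPC by 0.36 and 0.24.

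Donor-cell memory, the subject named in the title of the series, was measured on genes chosen in 1 random part of the donor and pOPC cells and read out in the other part. Of the log2 distance between donor and pOPC, genes specific to the donor kept 66.7% in MEF-2F (interval of the median over 721 genes 60.2 to 68.6), 54.6% in MEF-3F (49.7 to 59.3), 69.3% in PC-2F (64.1 to 74.9, 695 genes) and 64.1% in PC-3F (59.3 to 70.6). Genes specific to pOPC had covered 37.2% of the distance in MEF-2F (29.8 to 43.1, 832 genes), 41% in MEF-3F (41 to 47.3), 40.8% in PC-2F (37.7 to 46.6, 679 genes) and 43.9% in PC-3F (39.1 to 46.7). In MEF-3F the median equals its lower bound because many genes share 1 value. A library simulated at 50% of the distance read 60.1% acquired with MEF as donor and 53.3% with PC. For scale, unconverted donor profiles drawn at the depth of each converted library gave acquired values between -11.2% and 2.23%, and pOPC profiles gave retained values between -15.7% and 6.34%. In PC-2F 432 of 695 donor-specific genes were still at least 4-fold above pOPC, in PC-3F 388 of the same number, and in MEF-2F and MEF-3F 365 and 356 of 721. Fewer of the pOPC-specific genes were at least 4-fold above the donor. They numbered 156 (MEF-2F) and 217 (MEF-3F) of 832, and 207 (PC-2F) and 222 (PC-3F) of 679. All these values are of pooled libraries that join unlike cells, so a donor gene kept in few cells can read as largely kept. Cluster 8 of the joint clustering held 17.9% of PC-2F and 18.4% of PC-3F cells, with median pOPC weights per cell of 9.86% and 11.2%. Cluster 1 held 41 MEF-2F cells, with 0 Sox10 UMIs but Olig2 at 97.6 CPM. Sparc, which encodes a matrix protein of mesenchymal cells, was among the genes highest above pOPC in all 4, from 5197 CPM in PC-2F to 15082 CPM in MEF-2F against 0 in pOPC. In PC-2F and PC-3F (5522 CPM) it was also above PC (2845 CPM), so there it was higher and not only kept.

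**Figure D2:**
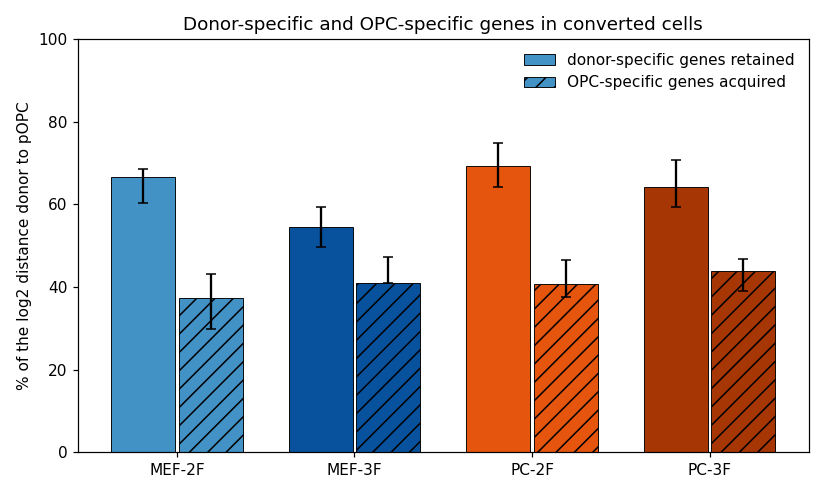
Donor-specific genes retained (plain bars) and OPC-specific genes acquired (hatched bars) in each converted library, as percent of the log2 distance between donor and pOPC; error bars are order-statistic 95% intervals of the median over genes. Retained values ran from 54.6% in MEF-3F to 69.3% in PC-2F, and acquired values from 37.2% to 43.9%.

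Cell by cell, each profile was fitted as a mixture of the pOPC, MEF and PC profiles over 2221 genes that separate them. The median pOPC weight was 32.9% in MEF-2F (quartiles 22.6 and 41.7), 52.3% in MEF-3F (41.2 and 60.2), 38.9% in PC-2F (28.4 and 47.4) and 39.1% in PC-3F (30.3 and 47.1). Held-out pOPC cells had a median of 100% with a lowest value of 96.8%, and held-out donor cells a median of 0% with highest values of 19.8% (MEF) and 5.23% (PC). The median MEF weight was 53% in MEF-2F, where the PC profile took 12.5%, and 42% in MEF-3F. In PC-2F and PC-3F the median PC weight was 31.3% and 34%, and the MEF profile, which is not their donor, took 24.6% and 25.4%. The file of MEF-3F joins 2 blocks of barcodes, and the median pOPC weight was 38.7% in the first (27 cells) and 56% in the second (95 cells); in MEF-2F it was 33.2% and 32.4%. With a least-squares fit in place of the mixture, the medians were 15.1% (MEF-2F), 45.2% (MEF-3F), 28.3% (PC-2F) and 28.8% (PC-3F).

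**Figure D3:**
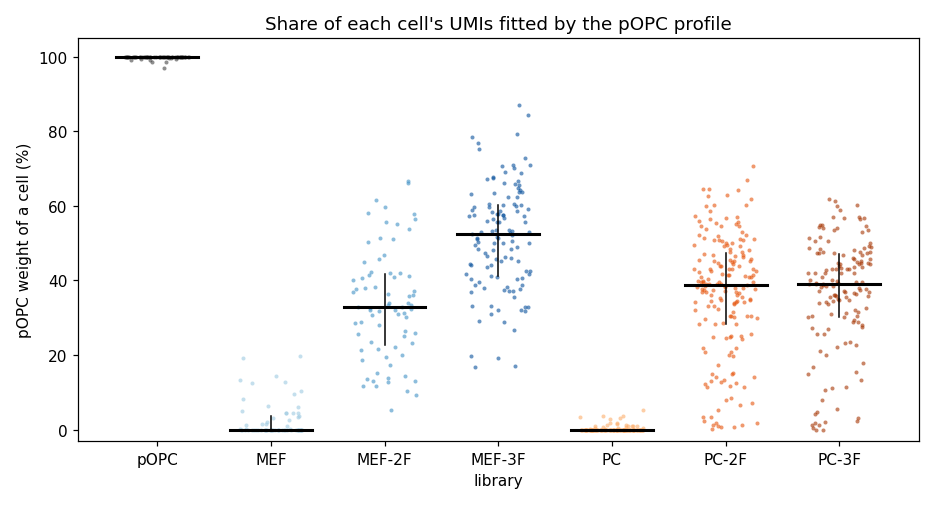
pOPC weight (percent) of each cell with at least 1000 UMIs, by library; points are cells, thick lines medians and thin lines quartiles, and pOPC, MEF and PC show only cells held out of the reference profiles. Medians of the converted libraries run from 32.9% to 52.3%, and their highest cell was at 87.1% in MEF-3F.

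Adding Nkx6-2 to Olig2 and Sox10 was examined by setting the 3-factor library of each donor against its 2-factor library. In the MEF pair the OPC list was higher with 3 factors, 8 of 17 members higher and 1 lower (median 1.20, percentile 100), and the Schwann and neural crest list lower, 6 of 9 members (median -1.68, percentile 0). The Schwann value goes in part with the mix of clusters: cluster 9 holds 50% of MEF-2F and 9.94% of MEF-3F cells, and within cluster 1 the list summed to 626 CPM in MEF-3F and 444 CPM in MEF-2F, within cluster 9 to 4553 and 6810 CPM. The OPC list summed to 5849.5 against 3203 CPM in cluster 1, but to 4204 against 5018 CPM in cluster 9. Ednrb alone was at 3139 and 3855 CPM of these cluster 9 sums. Olig1 was 22.6-fold higher (10.8 to 56.7), Fabp7 6.81-fold higher (4.70 to 10.2), Gpr17 7.78-fold higher (2.89 to 29.5) and the glycolytic and astrocytic gene Aldoc 21.8-fold higher (11.7 to 45.8). The neural crest factor gene Foxd3 was 11.9-fold lower (6.44 to 24.2), the osteopontin gene Spp1 12.4-fold lower (9.41 to 16.6) and Col1a1 9.20-fold lower (7.10 to 12.1). The fibroblast list was lower as well, with 8 of 21 members lower and none higher (median -0.77), while of the glycolysis and hypoxia genes 3 of 10 were higher and none lower (median 0.81). By size, 69 genes were at least 4-fold higher and 83 at least 4-fold lower in MEF-3F. Both files join 2 blocks of barcodes, and first block against first block gave 32 and 27 genes, an OPC median of 0.63 and a Schwann list median of -0.14, against 1.62 and -3.19 for the second blocks (37 and 119 genes). The values of both lists thus vary with the block, and the interval of the first-block OPC median, -0.69 to 1.95, includes 0.

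In the PC pair the libraries were closer on the OPC list (3 members higher and 5 lower of 18, median 0.22), with 72 genes at least 4-fold higher and 71 at least 4-fold lower in PC-3F. These numbers were 36 and 37 with libraries thinned to the smallest total, and 14 and 12 at a minimum of 100 CPM. Olig1 was 2.28-fold lower (1.83 to 2.86) in PC-3F and Olig2 2.17-fold lower (1.61 to 2.95). Sox2 was 7.10-fold lower (3.96 to 14), the adhesion gene Cntn1 at least 18.9-fold lower and the acute-phase gene Lcn2 5.54-fold lower (4.99 to 6.17). Insulin-like growth factor binding protein gene Igfbp2 was 26.6-fold higher (22 to 32.5), Col9a2 10.4-fold higher (8.72 to 12.6), the matrix gene Mgp 9-fold higher (7.92 to 10.2) and Lum 5.78-fold higher (4.51 to 7.46). Of the fibroblast list 8 members were higher and 3 lower of 22 (median -0.09), and the differentiation list had 1 of 18 lower and none higher.

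Cells of the 2 origins were then compared at matched factors, with the donors alongside. At 2 factors 385 genes were at least 4-fold higher and 235 at least 4-fold lower in MEF-2F than in PC-2F; at 3 factors the numbers were 468 and 281, and between the donors 596 and 446. At a minimum of 100 CPM they were 173 and 130, 127 and 115, and 174 and 148, and with libraries thinned to the smallest total 238 and 184 at 3 factors and 296 and 242 between the donors, so they are not ranked. The Schwann and neural crest list was higher in the MEF-derived library at 2 factors (6 of 9 members, median 3.83) and went both ways at 3 factors (4 higher and 2 lower of 8, median 1.33): Foxd3 was 125-fold higher (41.1 to 619.7) in MEF-2F than in PC-2F. The cartilage genes Col2a1 and Acan were 90.8-fold higher (67.2 to 125) and 3.90-fold higher (2.69 to 5.63) at 2 factors and 62.3-fold higher (43.7 to 92.1) and 7.30-fold higher (4.38 to 12.8) at 3. Immediate early and heat shock genes were higher in MEF-2F (11 of 13) and MEF-3F (12 of 14), as they were in MEF against PC (11 of 13). Cell cycle genes were lower (21 of 25 and 20 of 26, and 17 of 26 between the donors), and so were cholesterol synthesis genes (13 of 17, 11 of 17 and 12 of 17). The OPC list had a median of -0.44 at 2 factors and 1.57 at 3 factors (10 of 18 members higher and 4 lower); Pdgfra was 5.03-fold lower (3.72 to 6.93) and Sox2 17.5-fold higher (9.74 to 34.7) in MEF-3F than in PC-3F. Trf was 113-fold lower (76.8 to 176), Apod 119.7-fold lower (60.6 to 278) and Thy1 at least 21.7-fold lower in MEF-3F.

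Positional genes were compared as a mark of origin. The Hox genes, which mark position along the body axis, summed to 493 CPM (445 to 544) in MEF, 490.3 CPM (404 to 589) in MEF-2F and 442 CPM (384 to 507) in MEF-3F. They had no UMI in pOPC or PC, which allows up to 4.74 and 2.32 CPM, and summed to 30.9 CPM (21.7 to 42.5) in PC-2F and 23.6 CPM (13.2 to 39) in PC-3F. The limb and posterior genes Hoxd13 and Hoxd11 were at least 4.84-fold lower and at least 4.46-fold lower in MEF-3F than in MEF.

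Clustering all 1124 cells together without batch correction gave 9 clusters. Each held cells of pOPC, of MEF or MEF-derived, or of PC or PC-derived libraries alone, except cluster 6 with 109 PC and 8 MEF cells, so a cluster may be a library and not a cell type. The cluster of pOPC, left unnamed, had Stmn3 and the neuronal gene Elavl4 at the top of its genes, and of 12 fixed OPC markers 5 (Cntn1, Cspg5, Fabp7, Olig1 and Ptprz1) were at least 2-fold higher than in the other cells, none of them among its top 10 genes. No converted cell fell in this cluster or in the main cluster of its donor, which allows shares of up to 4.40% in MEF-2F and 2.04% in PC-2F (upper exact binomial bounds). MEF-2F cells split evenly, 41 in cluster 9, defined by Foxd3, Ngfr and Ednrb and Schwann-like by 3 of 5 fixed markers, and 41 in cluster 1, defined by Col2a1, Acan and Cytl1 and left unnamed; of MEF-3F cells 16 and 145 fell in these. Cluster 9 took 44.6% and 70.6% of the 2 blocks of MEF-2F and 25% and 4.96% of those of MEF-3F. Of PC-2F and PC-3F cells, 17.9% and 18.4% lay in cluster 8, defined by Mmp3, Ccl11, Dcn and Ccl2 over both libraries together (Mmp3 at 1496 CPM in its PC-2F and 34.5 CPM in its PC-3F cells), and the rest in a cluster of their own library, save 4 PC-3F cells. PC cells divided between cluster 2 (Krt20, S100a4; 181 cells) and cluster 6 (Krt19, Msln; 109 cells).

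**Figure D4:**
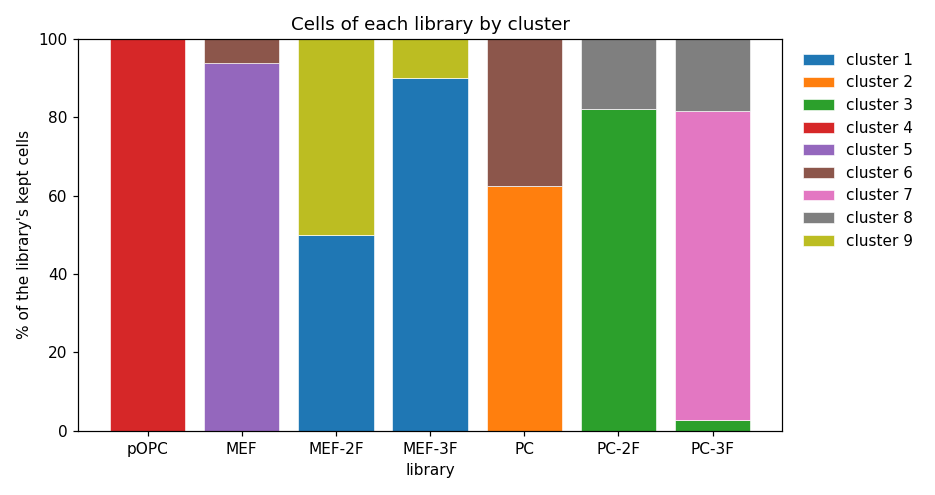
Percent of each library's kept cells in each of the 9 clusters (stacked bars, all cells clustered together). pOPC, the donors and the converted libraries of each donor share almost no cluster, and clusters 1 and 9 hold all cells of MEF-2F and MEF-3F.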

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

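The form of this search was chosen after a first form, based on list medians of opposite sign in the MEF and PC pairs, had returned nothing. It took each gene named in every comparison whose 3-factor library was at least 2-fold above its 2-factor library in 1 donor and at least 2-fold below it in the other, with both counting intervals excluding 1. Such a gene differs in direction between the donors, but with 1 library on each side the difference was not tested.

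Olig2 and Olig1 met this, the transduced factor gene and its neighbour on the same chromosome. The log2 ratio of MEF-3F over MEF-2F was 2.30 for Olig2 and 4.40 for Olig1, and that of PC-3F over PC-2F was -1.10 and -1.18. Within the blocks of MEF-3F, Olig1 stood at 154 CPM in the first and 817 CPM in the second, and Olig2 at 154 and 372 CPM. In MEF-2F the first block had 38.6 CPM of Olig1 and 82.7 CPM of Olig2, and the second block had no UMI of either, which allows up to 61 CPM (3 UMIs).

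The smooth-muscle actin gene Acta2 had log2 ratios of 4.23 in the MEF pair and -1.10 in the PC pair. Its level in MEF-3F came almost wholly from the second block, at 350.3 CPM against 11 CPM in the first. The collagen I genes went the other way, Col1a1 at -3.19 in the MEF pair and 1.05 in the PC pair, and Col1a2 at -1.72 and 1.52. Col1a1 was at 1164 and 2380.1 CPM in the blocks of MEF-2F and at 132 and 160.2 CPM in those of MEF-3F, so each block of MEF-2F was above each block of MEF-3F. Col1a2 was at 3293 and 3479 CPM in MEF-2F and 2139 and 733 CPM in MEF-3F. No explanation of these values was tested here.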

How the results depend on the processing

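Each block alone and the single most probable count of a code were alternatives chosen after the data had been seen, and the other 17 settings were planned. Of 598 values recomputed under 20 settings, 519 stayed within their interval or, for counts, within 1.5 times, and 79 moved further. No median whose interval excludes 0 changed sign. All values of the OPC list against pOPC, of the donor lists and of the clusters stayed within these bounds. So did every value with trimmed-mean factors, with CPM that leave out mitochondrial, ribosomal protein and the 20 most abundant genes, with the most probable count, with 500 UMIs per cell, at resolution 1.0 and without cell cycle genes. The values that moved follow. A minimum of 100 CPM leaves fewer genes to count by construction, and for the others the cause was not tested.

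With all libraries thinned to the smallest total, the OPC median against the donor was 5.64 (PC-2F) and 5.80 (PC-3F). Of genes 4-fold or more apart there were then 36 higher and 37 lower in PC-3F than PC-2F, 238 higher and 184 lower in MEF-3F than PC-3F, 296 higher and 242 lower in MEF than PC and 385 higher and 287 lower in MEF-3F than MEF. The numbers were 389 higher and 184 lower in PC-2F than PC and 386 higher and 249 lower in PC-3F than PC. With 5 CPM added to each level, the OPC median against the donor was 4.27 (PC-2F) and 4.68 (PC-3F), the oligodendrocyte median was 3.69 (PC-2F) and 3.43 (PC-3F) and the acquired share was 39.5% (MEF-3F) and 37.4% (PC-2F). Genes at least 4-fold apart then numbered 45 higher in PC-3F than PC-2F. With no minimum level, the OPC median against the donor was 5.27 (MEF-3F). Genes at least 4-fold apart then numbered 727 higher in MEF-2F than PC-2F. With a minimum of 100 CPM, the genes at least 4-fold apart numbered 29 higher and 48 lower in MEF-3F than MEF-2F, 14 higher and 12 lower in PC-3F than PC-2F, 173 higher and 130 lower in MEF-2F than PC-2F and 127 higher and 115 lower in MEF-3F than PC-3F. The numbers were 174 higher and 148 lower in MEF than PC, 284 higher and 187 lower in MEF-2F than MEF, 221 higher and 216 lower in MEF-3F than MEF and 245 higher and 134 lower in PC-2F than PC. The numbers were 260 higher and 166 lower in PC-3F than PC. With the mean of per-cell CPM, the Hox sum was 625 CPM (MEF-2F). Of genes 4-fold or more apart there were then 174 higher and 138 lower in MEF-3F than MEF-2F and 357 lower in MEF-2F than PC-2F. With all barcodes, the retained share was 68.9% (MEF-2F). Without barcodes called doublets, the retained share was 69.1% (MEF-2F) and 58.6% (PC-3F). With cells of 1000 UMIs or more, the acquired share was 37.5% (PC-2F). With another random split, the acquired share was 29.0% (MEF-2F) and the median pOPC weight was 41.2% (PC-2F). With genes chosen at 8-fold, the acquired share was 53.6% (MEF-3F). With informative genes 8-fold apart, the median pOPC weight was 56.6% (MEF-3F). With least squares in place of the mixture, the median pOPC weight was 15.1% (MEF-2F), 45.2% (MEF-3F), 28.3% (PC-2F) and 28.8% (PC-3F). With the first block alone in PC, MEF-2F and MEF-3F, the OPC median against the donor was 4.88 (PC-2F) and 5.31 (PC-3F), the oligodendrocyte median was 3.88 (PC-3F), the retained share was 61.4% (MEF-3F) and the acquired share was 48.0% (MEF-3F), 31.3% (PC-2F) and 33.7% (PC-3F). Genes at least 4-fold apart then numbered 32 higher and 27 lower in MEF-3F than MEF-2F, 189 higher and 141 lower in MEF-3F than PC-3F, 331 higher in MEF than PC and 359 higher and 200 lower in MEF-3F than MEF. The numbers were 390 higher in PC-2F than PC and 409 higher in PC-3F than PC. With the second block alone, the acquired share was 48.1% (MEF-2F). Of genes 4-fold or more apart there were then 37 higher in MEF-3F than MEF-2F, 171 higher and 72 lower in MEF-2F than PC-2F and 251 higher and 115 lower in MEF-2F than MEF.

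Depth limits the counts of genes, since a gene at the 20 CPM minimum has under 5 UMIs in MEF-2F. The sign of the pericyte list median against PC is open, as it ran from -0.98 to 1.25 in PC-2F and from -1.03 to 0.73 in PC-3F. At resolution 1.0 or without cell cycle genes there were 9 to 10 clusters, and at most 0.62% of MEF-3F cells and no cell of the other converted libraries fell in the pOPC cluster.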

Other observations

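Among the tests below, those of pericyte RNA, of cartilage cells apart and of the blocks were chosen after their results had been seen. The test of cartilage cells was first set on both libraries pooled and the test of blocks on both lists together, and they were split by library and by list, with a condition on spread added, once values were known; the test of pericyte RNA was split by library too, and its bound was changed from a fixed 20% to the counting intervals. The tests of both sexes, misplaced large counts, free RNA and depth were set beforehand.

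Further gene lists were compared with the donor of each library. The cell cycle list had medians of -0.90 (MEF-2F) and -0.43 (MEF-3F) against MEF and -0.04 (PC-2F) and -0.35 (PC-3F) against PC, and the p53 and senescence list -0.90, -1.29, -0.66 and -0.95. Pmaip1, a p53 target gene that promotes apoptosis, was 10.5-fold lower (4.42 to 32.8) in MEF-2F and 8.72-fold lower (4.87 to 17.2) in MEF-3F. The cholesterol synthesis list had medians of -0.27, -0.69, 0.21 and -0.36, the glycolysis and hypoxia list -1.96, -0.43, -0.06 and -0.53, and the interferon response list -1.10, -1.45, -0.12 and -0.43. In the PC library itself the interferon list had a median of 3.03 in the first block over the second. The astrocyte list stood at 0.03, 2.90, -0.86 and 1.89, and within it Aldoc was 373-fold higher (103 to 3093) in MEF-3F and 157-fold higher (60.8 to 581) in PC-3F, whereas Sox9, a glial and cartilage factor gene, was 25.5-fold lower (14.1 to 51.4) in PC-3F. The chondrogenic and osteogenic list stood at 2.40, 0.72, 0.59 and 0.86 over 4 measured genes in each. Of the imprinted growth genes 3 of 6 measured were higher and 0 lower in MEF-2F than in PC-2F (median 1.75), and 5 of 7 higher and 0 lower in MEF-3F than in PC-3F (median 2.93). The TGF-beta and YAP target list stood at -0.04 in PC-2F and 0.23 in PC-3F, and the sex-linked list at 0.82 in MEF-2F and -0.17 in MEF-3F over 3 measured genes. Of the 3 transduced factor genes 2 were measured, Olig2 and Sox10, too few for a median.

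Genes of the lists for other cell types were found in the donors. The microglia and macrophage list had medians of -4.10 in MEF-2F and -5.09 in MEF-3F against MEF (-1.49 and -2.48 at the limit that 0 UMIs allows), all 8 measured genes lower. Its gene Lyz2 was at least 33.1-fold lower in MEF-3F and stood at 9825 CPM in the 8 MEF cells of cluster 6. In PC-2F and PC-3F against PC no gene of this list was measured. The endothelial-list genes Flt1 (at least 49.6-fold lower in PC-3F), Kdr and Ly6c1 were all lower in PC-2F and PC-3F than in PC, with medians of -7.28 and -6.36 (-4.68 and -3.76 at the limit). They need not mark endothelial cells. Flt1 was seen in 60.8% of the cells of cluster 2, all from PC. Of 6 fixed endothelial markers 0 were at least 2-fold higher in cluster 2 than in the other cells, and Kdr alone was in cluster 6. Of the neuron list 4 genes were measured in MEF-2F and MEF-3F against MEF (medians -1.60 and -1.25) and 3 in PC-2F against PC (median 4.39). No myogenic gene was measured in the 4 comparisons with the donor, and of the epithelial list Krt19 alone, in those with PC.

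Within MEF-2F the cells of cluster 1 held 0 Sox10 UMIs of 112703 UMIs, which allows up to 26.6 CPM, while those of cluster 9 stood at 255 CPM. Olig2, the other transduced gene, went the other way, at 97.6 CPM in cluster 1 and 34 CPM in cluster 9. Olig1 was at 44.4 and 17 CPM. These levels rest on few counts, with 15 Olig2 UMIs in MEF-2F. The median pOPC weights of clusters 1 and 9 in MEF-2F were 23.2% and 36.4%. In MEF-3F cluster 1 had Sox10 at 255 CPM. The cells of cluster 8 had median pOPC weights of 9.86% in PC-2F and 11.2% in PC-3F, Sox10 at 9.15 and 13.8 CPM, and Spp1 at 17773 and 20814 CPM, against 214 and 917 CPM in the main clusters of these libraries. Some genes stood above both donor and pOPC: the collagen XI gene Col11a1, chosen after its values were seen, was at 5059, 6479, 4119.9 and 3101 CPM in MEF-2F, MEF-3F, PC-2F and PC-3F, against 617 in MEF, 44.1 in PC and 229 in pOPC.

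Xist, the RNA that silences 1 X chromosome in female cells, and Y-linked genes were both present in the MEF-derived libraries, at 56.4 and 104 CPM in MEF-2F and 61 and 63.2 CPM in MEF-3F, while MEF had 1 Xist UMI and 114 CPM of Y-linked genes. RNA of the pericyte libraries as pooled is argued against as the whole source. The share that their transcript Spp1 allows brings at most 1.82% of the Xist level in MEF-3F and 20.93% in MEF-2F. The upper bound in MEF-2F, 17.2 CPM, is below the lower bound of 30 CPM measured. RNA of the main clusters of PC-2F and PC-3F alone is not limited by Spp1 in MEF-2F. Their Spp1, at 214 and 917 CPM, was below that of MEF-2F (1618 CPM). In MEF-3F, with Spp1 at 131 CPM, the limit from Spp1 is much weaker. Xist and Trf argue against such RNA as the whole source. Xist stood at 24.5 and 23.7 CPM in these main clusters, below both MEF-derived libraries. Trf stood there at 6582 and 7143 CPM. It was at most 382 CPM in clusters 1 and 9 of MEF-2F and 194 CPM in those of MEF-3F, so such RNA can be only a small share. Embryos of both sexes among the MEF donors may be the source: 4 cells of both libraries held both kinds of UMI where independent placement gives 5.25, a ratio of 0.76, but random placement by depth gave 3 to 11 such cells, so the test leaves this open. The first block of MEF-3F had Xist at 66.2 CPM and no Y-linked UMI, which allows up to 33.1 CPM. The labels give no sex, so the design names no groups to set against this.

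Cartilage collagen genes were higher in MEF-2F and MEF-3F than in MEF, with Col2a1 at 3406 and 3044 CPM against 315 CPM. Large counts misplaced in decoding are argued against, since with counts held at 9 per cell Col2a1, Col9a1 and Col11a1 together were still 4.41-fold above MEF in the lower of the libraries. Free RNA spread over droplets is argued against as well: the tenth of cells richest in Col2a1 held 55.6% of its UMIs, 5.81 times the share of random placement. Cartilage cells apart from the converted cells would have a lower OPC list share in Col2a1-high cells. The ratio to the other cells was 0.95 in MEF-3F, against this. In MEF-2F it was 0.62, which cannot decide, because 1 gene, Ednrb, carries much of the list there. Ednrb was at 3855 of 5018 CPM in cluster 9 of MEF-2F, and at 231 of 3203 CPM in cluster 1, the cluster high in Col2a1. An effect of the transduced factors, which the design names, stays open as untested.

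The OPC list was higher and the Schwann and neural crest list lower in MEF-3F than in MEF-2F. Within cluster 9, though, the OPC list, most of it Ednrb there, summed to less in MEF-3F. Within cluster 1 the Schwann list summed to more in MEF-3F. The Schwann value thus goes in part with the mix of clusters, which those genes help to define, while the OPC list summed to more in MEF-3F within cluster 1, which holds 90.1% of its cells. Depth is argued against, because with libraries thinned to the smallest total the OPC median was 1.16 and the Schwann median -1.48. The blocks stay open for both lists: the lowest OPC median of the 4 pairs of blocks was 0.63 (-0.69 to 1.95) and the highest Schwann median -0.14 (-2.51 to 0.36), and the median of each list had the sign of the pooled value in all 4 pairs. The third factor Nkx6-2, the difference that the design names, is confounded with the library and stays open as untested.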
